A study of Mus musculus with 12 samples.

How the data were processed

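RNA from sorted immature myeloid cells was measured on 12 GeneChip Mouse Gene ST 2.0 arrays, 1 per sample, from 100 ng of total RNA each. The deposited values are on the log2 scale and were made by the authors with RMA (background correction, normalization across arrays and summary per transcript cluster) in Affymetrix Power Tools. The versions of both, and the library file behind them, are not given in the sources used here. The values were used as deposited. They are not centred per gene, and the raw intensities were not used here.

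The table held 41345 rows. A row was kept when its mean over the 12 arrays reached the 30th percentile of all rows, a log2 value of 4.70, which left 28941 rows. Gene symbols came from the probe annotation, and 23521 rows had 1 symbol, 1814 had several and 16010 had none. Current symbols were taken by gene ID from a reference gene table of assembly GRCm38.p6, used for names only: 23328 of the 23521 rows matched and 193 kept the annotation's symbol. Of the rows that passed the filter, 17828 had 1 symbol. For the 777 genes with several such rows the row with the highest mean was used, so that 16860 genes were tested, 2198 of them predicted or unnamed genes.

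The groups come from the sample labels: Tet2fl/fl and Tet2-/- cells at passage 2 and at passage 10, with 3 arrays each and replicate numbers 1 to 3 in every group. One linear model with a mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with 8 residual degrees of freedom and 3.33 prior ones. The contrasts were Tet2-/- minus Tet2fl/fl at each passage, passage 10 minus passage 2 in each genotype, and the difference between both genotype effects (the interaction). P-values are from limma's moderated test, two-sided, adjusted by Benjamini and Hochberg over the genes tested within each contrast, with 0.05 as the threshold.

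Sets of genes were tested with camera of limma at its preset correlation of 0.01, adjusted over the lists within a contrast. The same test with the correlation estimated from each list was run beside it, as was fry. The lists, 27 with 805 members in all, were fixed before the data were examined, as were the groups, tests, thresholds, the rule for naming genes and the alternatives, apart from those named as added. Of these members 661 were measured and 25 lists could be tested. The list of sex-linked genes had 1 measured member of 6, and the list of mitochondrial transcripts had 0 of 15, since the array annotation named no row for them or the rows lay below the filter.

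Tet2 was always named first. For each genotype comparison the rule named the 10 largest changes in each direction among the genes that passed and whose groups did not overlap, and for each passage comparison the 5 largest. Predicted and unnamed genes were left out of this ranking. From each list it named the members with the largest changes that passed or, where none passed, those nearest to passing. Genes named because they passed only with the replicate block were added to the rule after the data were seen.

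Replicate numbers were checked for pairing on each array's deviations from its group mean. The correlation was 0.201 to 0.517 for the 18 pairs of arrays with the same number in different groups and -0.369 to 0.0532 for the 36 pairs with different numbers. In 36 of 36 cases an array's best match in another group had its own number. A fit with the replicate number as a fixed block (6 residual and 3.93 prior degrees of freedom) is therefore given beside the results wherever it changes a call or moves a count by more than 1.5 times. The labels do not say whether the replicates were separate cultures, so p-values measure the spread among these samples.

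The alternatives were equal array medians, quantile normalization, no filter, a filter at the 50th percentile, limma's trend and robust options, array weights, the replicate number as a fixed or random block, the mean of a gene's rows, all rows without collapsing to genes, a fit to only the arrays compared, and leaving out each array. Added after the data were seen were leaving out 1 replicate number in all 4 groups and a contrast for the average of both genotype effects. The steps were tested on simulated data made from the arrays' own noise, with 200 changed genes among the 16860: at a fold change of 2 the test without the block recovered 88.1% of 67 genes for the genotype contrast at passage 2, 92.5% for the one at passage 10, 91.0% and 88.1% for the passage contrasts in Tet2fl/fl and Tet2-/- cells and 67.2% for the interaction, with at most 1 false call each. With the block it recovered 95.5%, 98.5%, 98.5%, 97.0% and 89.6%, with 7 to 14 false calls each. The simulation gave each replicate number the same deviation in all 4 groups, as the block assumes, so the higher recovery with it was built in. The remaining noise was drawn independently for each gene, so the false calls may differ on the real arrays.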

Results

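Gene expression was measured in mouse bone marrow cells that carried floxed Tet2 alleles, a Cre recombinase activated by tamoxifen (CreER) and a retrovirus for the leukaemia fusion protein AML1-ETO with GFP. Tet2 encodes an enzyme that oxidises methylated cytosine in DNA. After 3 rounds of replating, cells given 4-hydroxytamoxifen (4-OHT) at 200 nM became Tet2-/- and cells given ethanol stayed Tet2fl/fl. GFP-positive cells without CD11b or Gr1 and with CD16/32 were sorted at passage 2 and passage 10, with 3 arrays in each of the 4 groups. The array medians lay between log2 5.57 and 5.68, single values between 1.04 and 13.6, and arrays of a group correlated at 0.984 to 0.991 across all rows. In a principal component analysis the second component (19.09% of the variance) held all 6 Tet2-/- arrays between -18.1 and -6.72 and all 6 Tet2fl/fl arrays between 2.65 and 21.9. The first component (28.8%) ran from -27.0 to 0.81 at passage 2 and from -3.06 to 33.1 at passage 10. The number of arrays limits the precision. Values after ± are standard errors from the fit, with n = 3 arrays per group throughout, and differences are in log2 units.

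Tet2 itself did not differ between the genotypes in its array signal. Its mean log2 value was 9.97 in Tet2fl/fl and 9.94 in Tet2-/- cells at passage 2 (difference -0.03 ± 0.09, adjusted p = 0.952) and 9.88 and 9.83 at passage 10 (-0.05 ± 0.09, adjusted p = 0.921). The passage differences of Tet2 were -0.09 in Tet2fl/fl cells (adjusted p = 0.741) and -0.11 in Tet2-/- cells (adjusted p = 0.507). The array gives 1 value for the whole gene, so this value does not check the deletion. Of the 9 measured genes for the sorting markers and related surface proteins, none passed for genotype at either passage without the replicate block (1 and 2 at an unadjusted p under 0.05 at passage 2 and passage 10): Itgam (CD11b) differed by 0.12 at passage 2 and 0.20 at passage 10, Fcgr3 (CD16) by -0.10 and 0.18, and Ly6g (part of Gr1) by 0.09 and 1.32. Kit, in the same list, passed at both passages only with the block. Of 25 measured genes of the DNA methylation machinery, none passed for genotype at either passage with or without the block, with 5 and 2 at an unadjusted p under 0.05. For the average of both genotype effects, a contrast added after the data were seen, 1 of them was lower, Mbd1, named after its value was seen (-0.33, adjusted p = 0.0276). Of the sex-linked genes, Xist alone was measured above the filter, at 0.30 between the genotypes at passage 2 (adjusted p = 0.591) and 0.16 at passage 10 (adjusted p = 0.822).

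**Figure D1:**
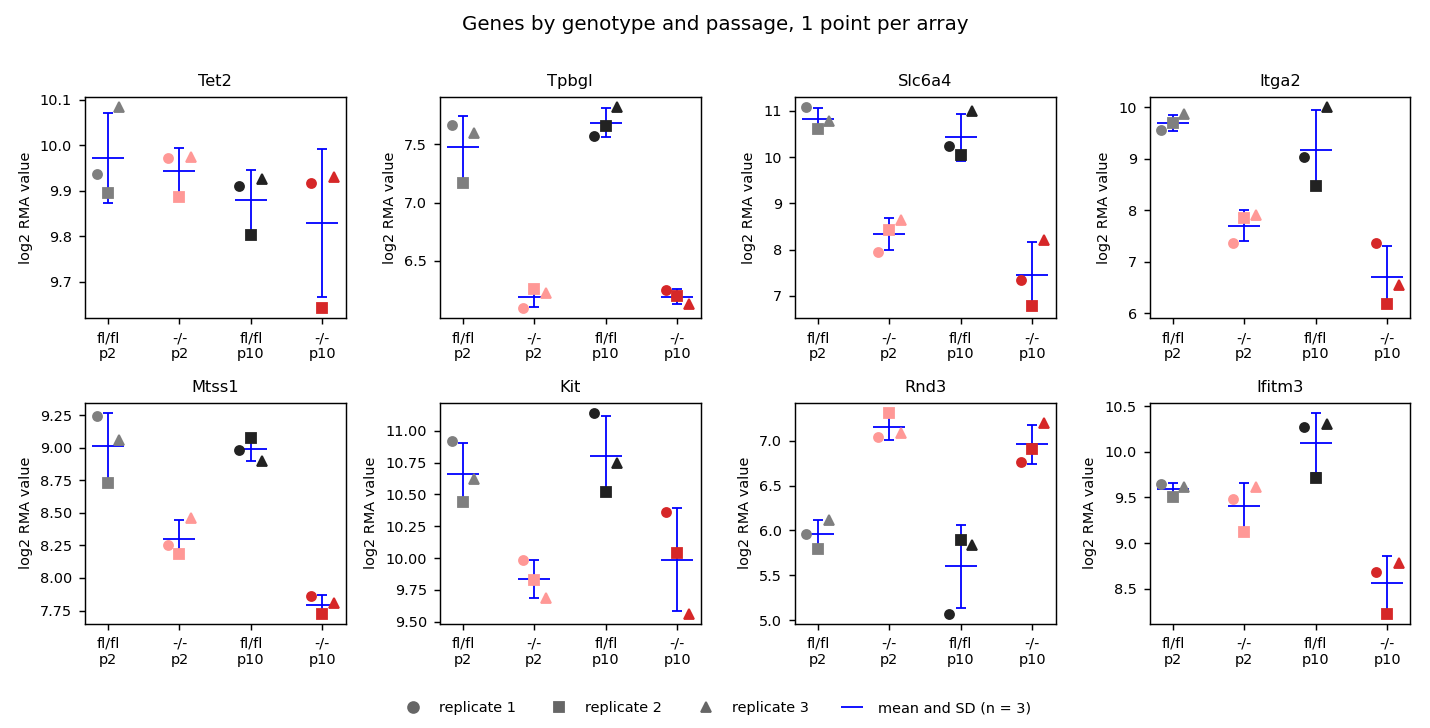
Log2 signal of 8 genes on each array, by group: points are arrays, with 3 per group, and bars are group means. Tet2 overlapped between the genotypes at both passages, while the difference of Slc6a4 between Tet2-/- and Tet2fl/fl cells was -2.48 at passage 2 and -2.98 at passage 10.

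The first comparison set Tet2-/- against Tet2fl/fl cells at passage 2. Treatment lasted 2 passages (4 days), with 4-OHT for Tet2-/- cells only. Effects of 4-OHT and Cre therefore cannot be told apart from loss of Tet2, here or in the other genotype comparisons. Tpbgl, a gene related to the trophoblast glycoprotein gene, was lower in Tet2-/- cells (-1.28 ± 0.12, adjusted p = 0.0067), in all 3 arrays against all 3. It was the only gene of 16860 to pass without the block in the fit described. In other fits 49 passed with array weights, 28 in a fit to only the arrays compared, 7 with a random block and 2 with the filter at the 50th percentile. With the replicate block 69 genes passed, 25 higher and 44 lower, Tpbgl among them. The lower ones included the serotonin transporter gene Slc6a4 (-2.48 ± 0.34, adjusted p = 0.0555, with the block 0.0149), the integrin gene Itga2 (-2.00, 0.134 and 0.0427), the receptor gene Kit (-0.83 ± 0.21, 0.201 and 0.0418) and Mtss1 (-0.71, 0.134 and 0.0422). The higher ones included Aff3 (1.22, 0.134 and 0.0418), Rnd3 (1.19, 0.121 and 0.0362) and the cytokine receptor gene Flt3 (0.63, 0.135 and 0.0418). At an unadjusted p under 0.05 there were 1677 genes, 724 higher and 953 lower. The groups did not overlap for 15.3% of genes, where chance gives 10% if the arrays can be exchanged freely. The pairing by replicate number puts that in doubt, here and below. Tpbgl missed the threshold without Tet2fl/fl p2 replicate 3, Tet2-/- p2 replicate 1 or Tet2-/- p2 replicate 3, each of which left 0 calls, with an adjusted p of up to 0.0759 and a difference of -1.43 to -1.18.

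At passage 2 genes of mast cells, basophils and eosinophils were lower as a list in Tet2-/- cells (adjusted p = 1.24e-06; adjusted p = 0.463 with an estimated correlation). Of its 28 measured members 22 had negative differences, with a median of -0.39, and the list means were 10.2 ± 0.107 (SD, n = 3) and 9.59 ± 0.108. None passed over all genes without the block, 12 had an unadjusted p under 0.05, 2 were lower with the block (Itga2 and Kit), and 9 were lower adjusted over the list alone. The eosinophil peroxidase gene Epx had the largest difference (-2.96, adjusted p = 0.178, with the block 0.0736). Genes of glycolysis and hypoxia were higher as a list (adjusted p = 0.00047; adjusted p = 0.981 with an estimated correlation): 25 of 26 were positive, with a median of 0.21, and none passed with or without the block or over the list alone, with 1 at an unadjusted p under 0.05 (Pdk1, 0.65, adjusted p = 0.468). Genes that restrain leukaemic or stem cell growth were lower as a list (adjusted p = 0.0277; adjusted p = 0.517 with an estimated correlation), with 32 of 47 negative and a median of -0.06. In that list 9 passed adjusted over the list alone, 14 had an unadjusted p under 0.05 and none passed over all genes without the block. Mtss1 and Socs2 (-0.52, adjusted p = 0.135) came closest. That list holds genes which the study may have picked from these samples, such as Mtss1 and Lxn, so neither its p-value nor its count is independent evidence. Its adjusted p was 0.052 with the block and 0.0679 with quantile normalization. It missed the threshold without Tet2fl/fl p2 replicate 1 (0.147) or 3 (0.055), Tet2-/- p2 replicate 1 (0.0762) or 3 (0.291) or Tet2fl/fl p10 replicate 2 (0.0586), and glycolysis and hypoxia did so without Tet2fl/fl p2 replicate 3 (0.106).

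At passage 10, after longer culture without Tet2, 38 genes passed, 21 higher and 17 lower in Tet2-/- cells, 34 of them by more than 1.5-fold. The largest named falls were those of Slc6a4 (-2.98 ± 0.34, adjusted p = 0.00589), Itga2 (-2.47, 0.0199), Lhfp (-1.94, 0.0199), the interferon-induced gene Ifitm3 (-1.54 ± 0.19, 0.00729), Tpbgl (-1.49, 0.00141), the potassium channel subunit gene Kcne3 (-1.42, 0.033), the growth factor gene Tgfa (-1.22, 0.0199) and Mtss1 (-1.19 ± 0.12, 0.00478). Adgrg6 (-0.98, 0.0304) and the transaminase gene Got1 (-0.94, 0.00729) fell as well. Nepn (2.57 ± 0.37), Rnd3 (1.36 ± 0.20), Slc26a9 (1.27), Mmp27 (1.24) and Sorl1 (1.05) rose, each with an adjusted p of 0.0199. Cyp2s1 (1.02, 0.0297), the transferrin receptor gene Tfr2 (0.83, 0.00546), the transcription factor gene Zbtb16 (0.82, 0.0199), the receptor gene Notch3 (0.80 ± 0.07, 0.00188) and Pglyrp2 (0.74, 0.0216) rose too. With the block 221 genes passed, 103 higher and 118 lower, and all 38 were among them. Passing only with the block were the high-affinity IgE receptor gene Fcer1a (-2.48, 0.0753 and 0.034), the tryptase gene Tpsab1 (-1.72, 0.0588 and 0.012), Grap2 (-1.66, 0.0556 and 0.038), Car8 (-1.78, 0.0608 and 0.0133) and Kit (-0.82, 0.161 and 0.0246), and on the higher side Cdh17 (2.10, 0.177 and 0.0278), Fxyd4 (1.54, 0.0694 and 0.0293) and Tigit (1.54, 0.26 and 0.0372).

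Without the block 1788 genes had an unadjusted p under 0.05 at passage 10, and the groups did not overlap for 16.4%, where chance gives 10%. The count became 70 without Tet2fl/fl p10 replicate 1 or without Tet2-/- p10 replicate 1, 21 without Tet2fl/fl p10 replicate 2, 13 without Tet2-/- p10 replicate 2 and 12 without Tet2-/- p10 replicate 3. It was 3 in a fit to only the arrays compared. Of the 20 ranked genes, 12 missed the threshold without Tet2-/- p10 replicate 2, 12 without Tet2-/- p10 replicate 3, 7 without Tet2fl/fl p10 replicate 2, and 3 each without Tet2fl/fl p10 replicate 1 or 3. The 7 that passed without any 1 of the 6 arrays were Tfr2, Notch3, Slc6a4, Ifitm3, Tpbgl, Mtss1 and Got1.

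**Figure D2:**
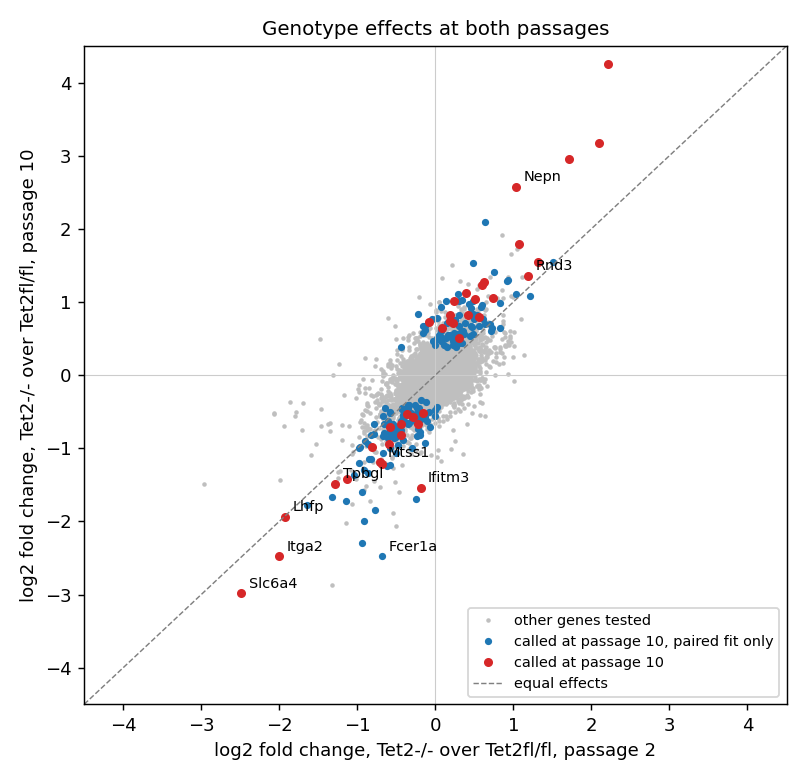
Log2 difference between Tet2-/- and Tet2fl/fl cells at passage 2 (horizontal) and passage 10 (vertical), 1 point per gene, with genes that passed at passage 10 marked. Of the 38 genes that passed at passage 10, 37 had the same sign at passage 2.

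Genes of glycolysis and hypoxia were the list with the smallest p-value at passage 10 (adjusted p = 2.74e-13; adjusted p = 0.611 with an estimated correlation). Their mean was 9.98 ± 0.391 (SD, n = 3) in Tet2fl/fl and 10.5 ± 0.112 in Tet2-/- cells. Tet2fl/fl p10 replicate 1 (10.425) lay within the range of the Tet2-/- arrays (10.405 to 10.614), while replicates 2 and 3 lay at 9.68 and 9.85. Of the genes, 25 of 26 were positive with a median of 0.45. Over all genes none passed without the block, 17 had an unadjusted p under 0.05, and 13 rose adjusted over the list alone, while with the block the aldolase gene Aldoc passed (0.97 ± 0.23, adjusted p = 0.117 and 0.0326). The hexokinase gene Hk2 came next (0.60, 0.194 and 0.071). Genes of mast cells, basophils and eosinophils were again lower (adjusted p = 0.00338; adjusted p = 0.611 with an estimated correlation), with 19 of 28 negative and a median of -0.30. One fell over all genes (Itga2), 4 were lower with the block, and 5 fell adjusted over the list alone. Genes of the type I interferon response were lower (adjusted p = 0.0184; adjusted p = 0.678 with an estimated correlation), with 24 of 31 negative and a median of -0.18. None of these passed without the block or over the list alone, 4 had an unadjusted p under 0.05, and with the block Slfn5 passed (-0.98, 0.253 and 0.035). Stress and immediate early genes were higher (adjusted p = 0.0217; adjusted p = 0.611 with an estimated correlation; 0.0527 with the block), with 18 of 26 positive and a median of 0.15. None of them passed without the block or over the list alone, 6 had an unadjusted p under 0.05, and Nr4a1, lower against the list's direction, passed with the block (-0.45, 0.232 and 0.0394). The interferon list missed the threshold without Tet2fl/fl p10 replicate 1 (0.468) or Tet2-/- p10 replicate 3 (0.115). The stress list missed it without Tet2fl/fl p10 replicate 1 (0.142) or 2 (0.0567) or Tet2-/- p10 replicate 1 (0.0507) or 3 (0.115).

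**Figure D3:**
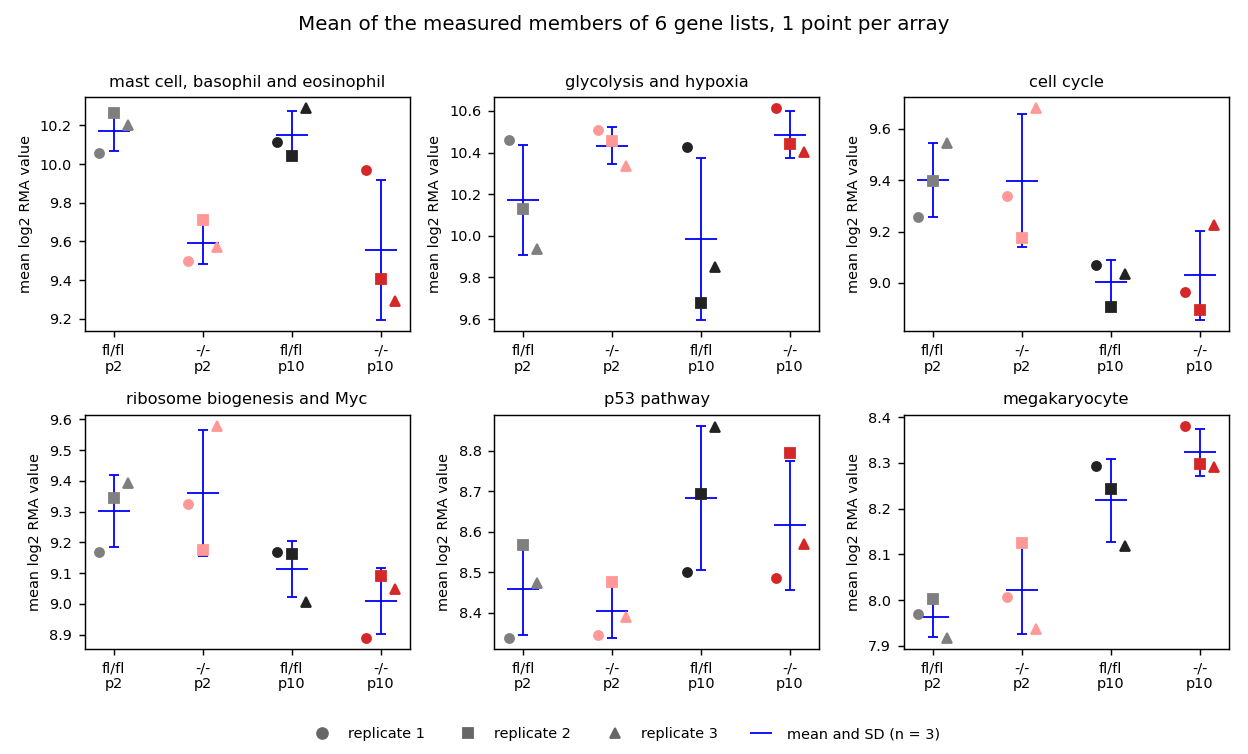
Mean log2 signal of the measured members of 6 gene lists on each array, by group, with bars at group means of 3 arrays. The mast cell, basophil and eosinophil list averaged 10.2 and 9.59 in Tet2fl/fl and Tet2-/- cells at passage 2 and 10.1 and 9.56 at passage 10.

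The genotype effects at passage 2 and passage 10, which share no arrays, correlated across the 16860 genes at r = 0.58 (Pearson) and 0.42 (Spearman), where genes are not independent replicates. Among the 99 other combinations of splits of the arrays within the passages, r reached 0.579. Of the 38 genes that passed at passage 10, 37 had the same sign at passage 2, 28 of these with an unadjusted p under 0.05. With the block 13 genes were higher and 25 lower at both passages, where independent lists would share 0.153 and 0.308, and 1 changed in opposite directions. The lists are not independent, since both contrasts share 1 estimate of each gene's spread and the arrays pair by replicate number across passages. The numbers for independent lists are therefore too low a standard. For the average of both genotype effects 290 genes passed, 111 higher and 179 lower (912 with the block). Slc6a4 (-2.73), Itga2 (-2.24), Tpsab1 (-1.43), Mtss1 (-0.95, adjusted p = 0.00103), Lxn (-0.93, adjusted p = 0.00973), the prostaglandin synthase gene Hpgds (-0.91, adjusted p = 0.0102) and Kit (-0.82, adjusted p = 0.022) fell, and Nepn (1.81), Rnd3 (1.27), Aff3 (1.15) and the interleukin 1 receptor gene Il1r1 (0.88) rose. In this contrast 302 genes had all 6 Tet2-/- arrays on 1 side of all 6 Tet2fl/fl arrays, and 149 of the 302 passed. Chance would give 36.5 if all 12 arrays could be exchanged freely, which passage and the pairing by replicate number put in doubt. With equal array medians the share of higher genes among those that passed went from 38.3% to 23.3%. The count of 290 was 496 without Tet2fl/fl p10 replicate 1, 160 without its replicate 3, 125 and 120 without Tet2-/- p10 replicates 2 and 3, 116 and 126 without Tet2fl/fl p2 replicates 2 and 3, and 98 and 139 without Tet2-/- p2 replicates 1 and 2.

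Passage in Tet2fl/fl cells asked what longer culture changed without deletion. No gene passed in limma's test without the block or with a random block, against 1722 at an unadjusted p under 0.05 (964 higher, 758 lower), and 7 passed with the fixed block. These were Gsn (0.57), Slco4c1 (-1.44), Lgr4 (-0.85), Lrrk1 (-0.74), the cell division genes Anln (-0.65) and Cdkn3 (-0.64) and, outside the naming rule, the mitotic kinesin gene Kif11 (-0.63), each with an adjusted p of 0.0466 with the block. Without the block the nearest were Hapln1 (-1.79 ± 0.27), the histone gene H4c9 (-0.52) and Trp53i11 (-0.71), with an adjusted p of 0.317 for Hapln1. The groups did not overlap for 14.5% of genes, where chance gives 10%.

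As a list, cell cycle genes were lower at passage 10 in Tet2fl/fl cells (adjusted p = 2.94e-23; adjusted p = 0.518 with an estimated correlation), with 40 of 44 negative and a median of -0.42. The mitotic checkpoint gene Bub1 (-0.68) and the ribonucleotide reductase gene Rrm2 (-0.61) came closest, both with an adjusted p of 0.401. No member passed over all genes without the block, 29 had an unadjusted p under 0.05, 1 was lower with the block and 22 were lower adjusted over the list alone. Ribosome biogenesis and Myc genes were lower (adjusted p = 7.92e-09; adjusted p = 0.696 with an estimated correlation; 32 of 33 negative, median -0.21), as were glycolysis and hypoxia (adjusted p = 0.00135; 0.706; 23 of 26, -0.18), late granule genes of maturing neutrophils (adjusted p = 0.0114; 0.706; 21 of 24, -0.40) and cholesterol synthesis (adjusted p = 0.0173; 0.706; 14 of 19, -0.08). P53 pathway genes were higher (adjusted p = 0.000371; 0.696; 23 of 26 positive, median 0.22), as were megakaryocyte genes (adjusted p = 0.0173; 0.518; 17 of 19, 0.17) and genes of dendritic cells and MHC class II (adjusted p = 0.0353; 0.623; 16 of 19, 0.16), where the second p in each case is the adjusted p with an estimated correlation. Ddit4 (0.71) and Trp53inp1 (0.50) of the p53 list and Ppbp (1.77) of the megakaryocyte list were the nearest members, each with an adjusted p of 0.401, and no member of these 7 lists passed with or without the block, with 0 to 8 of each at an unadjusted p under 0.05. With the block type I interferon genes were higher as well (adjusted p = 0.0266; 0.0713 without it; 0.653 with it and an estimated correlation). With quantile normalization dendritic cell and MHC class II genes missed the threshold (0.0516). Only the cell cycle and ribosome lists passed without each array: dropping Tet2fl/fl p2 replicate 1 lost dendritic cell (0.085), megakaryocyte (0.0605), p53 (0.0749) and glycolysis genes (0.486), dropping Tet2fl/fl p2 replicate 2 lost cholesterol synthesis (0.257), and dropping Tet2fl/fl p2 replicate 3 lost late granule (0.615) and dendritic cell genes (0.198). Dropping Tet2fl/fl p10 replicate 1 lost megakaryocyte (0.0687) and cholesterol genes (0.192), dropping replicate 2 of that group lost late granule (0.957, with the other sign), dendritic cell (0.11), megakaryocyte (0.0669) and glycolysis genes (0.397), and dropping its replicate 3 lost p53 and glycolysis genes (0.0598 each).

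Passage in Tet2-/- cells changed 503 genes, 211 higher and 292 lower at passage 10, 182 of them by more than 1.5-fold. Nepn (1.65 ± 0.37, adjusted p = 0.0419), the complement gene C4a (1.36, 0.0398), Hacd4 (1.13, 0.0246), the stress-induced mTOR inhibitor gene Ddit4 (1.12 ± 0.17, 0.0224) and Acoxl (1.04, 0.0375) rose most. Sgms2 (-1.87, 0.0445), the cholesterol 25-hydroxylase gene Ch25h (-1.59, 0.0272), the receptor gene Tacr1 (-1.48, 0.0224), Dleu2 (-1.26, 0.0364) and Wls (-1.20, 0.0313) fell most. With the block 1339 genes passed, 550 higher and 789 lower, and all 503 were among them. The neutrophil genes S100a8 (-2.72, 0.117 and 0.0208), Ngp (-2.03, 0.079 and 0.0293) and Elane (-1.69, 0.191 and 0.038) passed only with the block, as did Ppbp (1.73, 0.0532 and 0.0372), Zfpm1 (0.48, 0.0512 and 0.0113) and Flt3 (-0.46, 0.0602 and 0.0224). At an unadjusted p under 0.05 there were 3638 genes, and the groups did not overlap for 28.3%, where chance gives 10%. Of those that passed 41.9% were higher, against 60.2% with equal array medians and 59.9% with quantile normalization. The count was 387 without Tet2-/- p2 replicate 2, 2 without Tet2-/- p10 replicate 1, and 0 without Tet2-/- p2 replicate 1, Tet2-/- p2 replicate 3, Tet2-/- p10 replicate 2 or Tet2-/- p10 replicate 3. It was also 0 in a fit to only the arrays compared. Of the 21 genes named because they passed, 10 missed the threshold without Tet2-/- p2 replicate 2 and at least 20 without each of the other 5.

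In Tet2-/- cells ribosome biogenesis and Myc genes were lower at passage 10 (adjusted p = 4.18e-13; adjusted p = 0.70 with an estimated correlation), with 33 of 33 negative and a median of -0.31. Of these 3 fell over all genes, among them the nucleolar genes Nop58 (-0.75, adjusted p = 0.0257) and Nop56 (-0.65, 0.0313), 9 with the block, and 15 adjusted over the list alone. Cell cycle genes were lower (adjusted p = 2.77e-12; adjusted p = 0.70 with an estimated correlation), with 41 of 44 negative and a median of -0.41. Among them 4 fell, including the mitosis genes Cenpe (-0.76, 0.0462) and Bub1 (-0.70, 0.0442), 18 were lower with the block and 22 changed adjusted over the list alone. The methylation reader gene Uhrf1 fell (-0.60, 0.0436). Megakaryocyte genes were higher (adjusted p = 0.0253; adjusted p = 0.632 with an estimated correlation; 17 of 19 positive, median 0.22), with none passing over all genes without the block, 5 at an unadjusted p under 0.05, 4 with the block and 5 adjusted over the list alone. Myeloid transcription factor genes were higher (adjusted p = 0.0253; 0.70 with an estimated correlation; 35 of 45, median 0.14), with Stat3 rising (0.35, 0.0437). P53 pathway genes (adjusted p = 0.0402; 0.855 with an estimated correlation; 19 of 26, median 0.19) included 2 that rose, Ddit4 and Btg2 (0.99, 0.043), and stress and immediate early genes were higher (adjusted p = 0.0402; 0.70 with an estimated correlation; 20 of 26, median 0.25; 0.0527 with the block) although Hsp90aa1 fell (-0.35, 0.0464). With the block late granule (adjusted p = 0.0271, 0.224 without it) and early granule genes (0.0489, 0.113 without it) were lower as well. With the block and an estimated correlation their adjusted p was 0.753 each. Dropping Tet2-/- p2 replicate 1 lost p53 and myeloid transcription factor (0.109 each) and stress genes (0.115), dropping Tet2-/- p2 replicate 3 lost megakaryocyte, p53 and myeloid transcription factor (0.0996 each) and stress genes (0.144), and dropping Tet2-/- p10 replicate 1 lost myeloid transcription factor (0.0556) and stress genes (0.0626). Dropping Tet2-/- p10 replicate 2 lost p53 (0.195) and dropping Tet2-/- p10 replicate 3 lost stress genes (0.119); p53 genes also missed the threshold with equal array medians (0.0551), as did stress genes there, with quantile normalization (0.0743) and with a random block (0.0585).

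The passage effects in both genotypes, which share no arrays, correlated across genes at r = 0.63 (Pearson) and 0.58 (Spearman), and other splits within the genotypes reached 0.602 in size (Pearson). Among the 16 combinations that parted all pairs of replicate numbers, the largest other was 0.518 in size. These are too few for a share under 0.05. Of the 503 genes that passed in Tet2-/- cells, 484 had the same sign in Tet2fl/fl cells, 271 of these with an unadjusted p under 0.05. Whether the genotype effect changed between the passages was tested as an interaction. No gene passed in limma's test, against 543 at an unadjusted p under 0.05. The nearest included Prickle3 (0.81), Tfr2 (0.64) and Nrm (0.75), each with an adjusted p of 0.999, and with the block Ifitm3 alone passed (-1.35 ± 0.27, 0.999 and 0.0432). As lists, ribosome biogenesis and Myc genes moved down relative to the other genotype (adjusted p = 0.000233; adjusted p = 0.681 with an estimated correlation; 29 of 33 negative, median -0.13), and type I interferon genes did so too (0.0205; 0.681; 21 of 31, -0.15). Glycolysis and hypoxia (0.000477; 0.681; 25 of 26 positive, 0.25), stress and immediate early (0.00419; 0.632; 22 of 26, 0.17) and myeloid transcription factor genes (0.0123; 0.632; 34 of 45, 0.09) moved up. No member of these 5 lists passed with or without the block or over the list alone, with 0 to 3 of each at an unadjusted p under 0.05. Without Tet2fl/fl p2 replicate 1 all 5 lists missed the threshold (0.0987, 0.361, 0.29, 0.0835 and 0.0835 in that order). Other losses were ribosome (0.274), glycolysis (0.0511), myeloid (0.1) and stress genes (0.0609) without Tet2-/- p2 replicate 3, glycolysis and myeloid genes (0.21 each) without Tet2fl/fl p10 replicate 2, and interferon (0.0549) and myeloid genes (0.0548) without Tet2fl/fl p2 replicate 3. Myeloid genes missed it without Tet2-/- p2 replicate 1 (0.0593), and interferon genes without Tet2-/- p2 replicate 2 (0.126), Tet2fl/fl p10 replicate 1 (0.379) or Tet2-/- p10 replicate 3 (0.153).

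The other lists did not pass without the block in any comparison: stem and progenitor, monocyte and macrophage, erythroid, B lymphoid, lymphoid cells of the T, NK and innate types, sort gate, NF-kB and inflammatory, DNA methylation machinery, cytokine receptors, germline genes with methylated promoters, and cell adhesion and migration, with early granule genes passing only as given above. Among the lists that did not pass, the adjusted p ran from 0.0882 (monocyte and macrophage) to 0.966 for genotype at passage 2, from 0.0603 (ribosome biogenesis and Myc) to 0.957 at passage 10, from 0.0713 to 0.934 for passage in Tet2fl/fl cells, from 0.113 to 0.931 in Tet2-/- cells and from 0.109 (erythroid) to 0.726 for the interaction. With an estimated correlation 0 of the 125 list tests passed, against 5 at an unadjusted p under 0.05, and fry called 1 (megakaryocyte genes with passage in Tet2-/- cells, adjusted p = 0.0321) with 16 at an unadjusted p under 0.05. The median, the mean and the test direction of a list had 1 sign in all 26 calls and differed in 28 of the other 99 tests, such as late granule genes for genotype at passage 10 (median -0.07, mean -0.23, test upward).

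**Figure D4:**
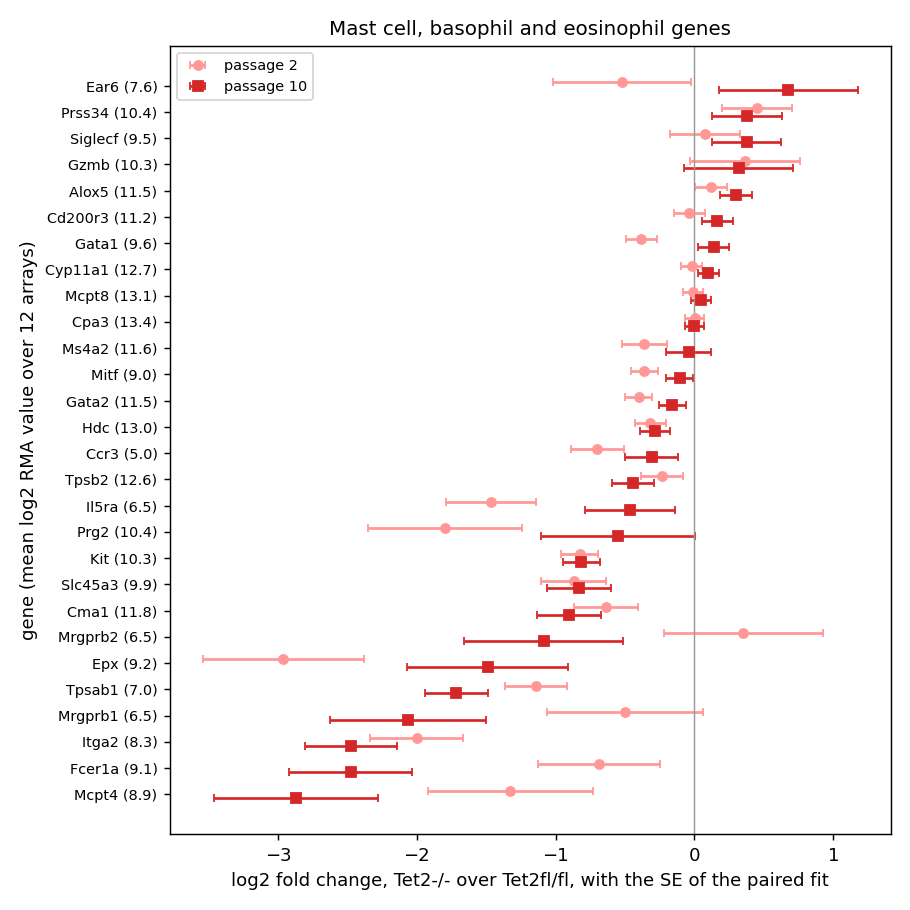
Log2 difference between Tet2-/- and Tet2fl/fl cells at passage 2 and passage 10 for the 28 measured members of the mast cell, basophil and eosinophil list, with bars of 1 standard error from the fit with the replicate block. Itga2 (-2.00 and -2.47) passed at passage 10, and with the block at both passages, Kit (-0.83 and -0.82) passed at both only with the block, and the basophil genes Cd200r3 (-0.04 and 0.16) and Prss34 (0.45 and 0.38) did not pass.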

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

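The tests of explanations, and the counts over other assignments of the arrays, were chosen after the results were seen. Tet2-/- and Tet2fl/fl cells differed in how 5 gene lists moved between passages, by the interaction of genotype and passage. Ribosome biogenesis and Myc genes (adjusted p = 0.000233) and type I interferon genes (0.0205) moved down, and glycolysis and hypoxia (0.000477), stress and immediate early (0.00419) and myeloid transcription factor genes (0.0123) moved up. With an estimated correlation none passed (0.632 to 0.681), with 0 of 25 lists at an unadjusted p under 0.05. All 5 missed the threshold without Tet2fl/fl p2 replicate 1 (0.0835 to 0.361), and fewer did without other single arrays, as given with the interaction. Of 100 assignments of the 12 arrays to 4 groups, the real one included, 54 called at least 5 lists, up to 13. Of 100 that exchanged arrays only within a replicate number, 60 did, also up to 13, where some carry the genotype or passage effect into the interaction. Chance is not excluded for the list count. For genes limma called 0 (543 at an unadjusted p under 0.05; 1 with the replicate block), which all 100 assignments must reach, so that count tests nothing.

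Ifitm3, an interferon-induced antiviral gene, differed between the genotypes by -0.19 at passage 2 and by -1.54 at passage 10. Its interaction of -1.35 was the only one to pass with the replicate block (adjusted p = 0.0432; 0.999 without it).

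Rows of the array without a single gene name, which entered no comparison of genes, also passed when all rows were tested: 2 of 11113 for genotype at passage 10, both higher in Tet2-/- cells, and 114 for passage in Tet2-/- cells, 10 higher and 104 lower. The 2 rows at passage 10 (2.74, adjusted p = 0.0101, and 1.48, adjusted p = 0.044) were not assigned to a gene. The first of them carries several symbols, among them that of Gm2022, an Eif1a-like gene described under the other observations. The second carries none. The rows had correlations of 0.994 and 0.960 with the Eif1a-like genes described there. Rows and genes were both picked for higher values in Tet2-/- cells at passage 10. Where a correlation includes that difference, a high value was likely beforehand, so these values do not assign the second row.

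Passage called 503 genes in Tet2-/- cells and 0 in Tet2fl/fl cells (limma; 3638 and 1722 at an unadjusted p under 0.05; 1339 and 7 with the replicate block), but the interaction of genotype and passage called 0, so the effects were not shown to differ. The passage effect may have been of 1 size in both genotypes and have straddled the threshold. In genes chosen in Tet2-/- cells from 2 replicate numbers, 500 each time, the left-out pair moved by 0.501 in Tet2-/- and 0.305 in Tet2fl/fl cells on average, a ratio of 0.609. In genes chosen in Tet2fl/fl cells it moved by 0.369 in Tet2-/- and 0.231 in Tet2fl/fl cells, a ratio of 0.627. By replicate number, with genes chosen in Tet2-/- cells, the Tet2-/- and Tet2fl/fl values were 0.513 and 0.16, 0.427 and 0.239, and 0.564 and 0.517. Both ratios lie below 1, but the third pair leaves this open. In the Tet2-/- cells the left-out pairs moved by at least 0.427, while the array medians within a pair differed by at most 0.0759 in size. The deposited values thus held no shift of every gene by 1 amount that was large enough to give this movement. RMA had normalized the arrays beforehand, so close medians were set in advance, and the comparison says nothing of the arrays before normalization. A shift that varies with the signal was not tested. An earlier test of the spread of each genotype's own arrays (median SD 0.130 in Tet2-/- and 0.143 in Tet2fl/fl cells, with 0 calls each and 3702 and 1346 genes at an unadjusted p under 0.05) was set aside because both contrasts share 1 pooled spread. A test with equal array medians (327 and 0 genes) was set aside too, because a Tet2fl/fl count of 0 decides little. The count of 503 fell to 0 without Tet2-/- p2 replicate 1, Tet2-/- p2 replicate 3, Tet2-/- p10 replicate 2 or Tet2-/- p10 replicate 3, and was 2 without Tet2-/- p10 replicate 1 and 387 without Tet2-/- p2 replicate 2.

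For comparisons of 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Passage in Tet2-/- cells gave 503 genes against at most 0 in the other splits, so that 1 of 10 gave as many, and passage in Tet2fl/fl cells gave 0 against 0 (10 of 10). Genotype gave 1 gene at passage 2 against 0 (1 of 10) and 38 at passage 10 against 1 (1 of 10). For lists, the real splits gave 3, 4, 8 and 6 for genotype at passage 2, genotype at passage 10, passage in Tet2fl/fl and passage in Tet2-/- cells, and the highest other splits gave 10, 8, 11 and 11 (7, 9, 2 and 4 of 10 gave as many). The highest list counts were 8, 5, 7 and 10 among other splits that parted all 3 pairs of replicate numbers, and 10, 8, 11 and 11 among the rest. Why other splits called so many lists was not tested, and the preset correlation, without which no list passed in camera, is not excluded as the source.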

How the results depend on the processing

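Leaving out 1 replicate number in all 4 groups and the average of both genotype effects were chosen after the results were seen. Counts of genes are in the order genotype at passage 2, genotype at passage 10, passage in Tet2fl/fl cells, passage in Tet2-/- cells and interaction, which were 1, 38, 0, 503 and 0 (1677, 1788, 1722, 3638 and 543 at an unadjusted p under 0.05). They were 1, 46, 0, 327 and 0 with equal array medians, 1, 42, 0, 669 and 0 with quantile normalization, 1, 32, 0, 218 and 0 with no filter on dim rows and 2, 61, 0, 757 and 0 with the filter at the 50th percentile. They were 1, 66, 0, 710 and 0 with the trend and robust options, 49, 97, 0, 1728 and 0 with array weights, 69, 221, 7, 1339 and 1 with the fixed replicate block and 7, 124, 0, 1047 and 0 with the random one. The mean of a gene's rows gave 1, 45, 0, 503 and 0, and all rows without collapsing 1, 14, 0, 285 and 0. With only the arrays compared the first 4 were 28, 3, 0 and 0, where fewer arrays set the spread. Leaving out replicate number 1 of all 4 groups, with the block, gave 0, 163, 4, 56 and 1, leaving out number 2 gave 1, 2, 0, 0 and 0, and leaving out number 3 gave 2, 33, 2, 0 and 0. The average of both genotype effects, added as well, called 290, against 181 to 427 across scaling, filter, moderation and row choices, 776 with array weights, 912 and 678 with the fixed and random block, 98 to 496 without single arrays and 478, 42 and 96 without replicate number 1, 2 or 3. Where the fixed block changed the call of a gene or list given, its value stands beside it, and it changed no other call of those given. The cause of these moves was not tested.

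Leaving out each array in turn gave 0 to 1 gene for genotype at passage 2 (0 without Tet2fl/fl p2 replicate 3 or Tet2-/- p2 replicate 1 or 3), 12 to 70 at passage 10, 0 to 387 for passage in Tet2-/- cells, and 0 throughout for passage in Tet2fl/fl cells and the interaction; the values array by array stand with each comparison. Lists called ranged from 2 to 6, 3 to 8, 4 to 9, 2 to 8 and 0 to 7 in the same order, where all arrays gave 3, 4, 8, 6 and 5. The highest and lowest came without Tet2-/- p2 replicate 2 (6), Tet2fl/fl p10 replicate 3 or Tet2-/- p10 replicate 2 (8), Tet2fl/fl p10 replicate 2 (4), Tet2-/- p2 replicate 3 (2) and Tet2fl/fl p2 replicate 1 (0), with 5, 3, 3 and 2 lists for passage in Tet2fl/fl cells without Tet2fl/fl p2 replicate 1, passage in Tet2-/- cells without Tet2-/- p2 replicate 1, and the interaction without Tet2fl/fl p2 replicate 3 or Tet2-/- p2 replicate 3. With an estimated correlation 0 lists were called in each comparison (2, 0, 2, 1 and 0 at an unadjusted p under 0.05), and fry called 0, 0, 0, 1 and 0 (4, 2, 4, 6 and 0). Of the 26 list calls, 7 passed without each array: cell cycle and ribosome biogenesis with passage in both genotypes, the mast cell, basophil and eosinophil list at both passages, and glycolysis and hypoxia at passage 10. Late granule genes with passage in Tet2fl/fl cells changed sign without Tet2fl/fl p10 replicate 2 (adjusted p = 0.957, against 7.84e-05 to 0.957 over all arrays left out, and 0.0114 with all), and the cause was not tested.

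The named genes were compared first across the settings other than leaving out an array or a replicate number. There 4224 values kept their direction and side of the threshold, 175 passed only under the alternative and 63 only with all settings as reported. With single arrays left out, or 1 replicate number left out of all 4 groups with the block, these numbers were 4329, 35 and 247. No called gene changed direction. Of 8065 values that did not pass, 293 had the other sign and count among those kept. For lists 96 kept their call and 60 lost it under other settings, and 257 kept it, 54 lost it and 1 changed sign with arrays left out. Signals near the background or near the top of the arrays at 13.6 limit what differences can be seen.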

Other observations

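All tests in this part were chosen after the results were seen. The mast cell, basophil and eosinophil list was lower in Tet2-/- cells at both passages with the preset correlation but not with an estimated one (adjusted p = 0.463 at passage 2 and 0.611 at passage 10). Of 9 mast cell genes, sorted from the fixed list after the values were seen, 8 were lower at passage 2 (median -0.64) and 9 at passage 10 (median -0.91). Kit (-0.83 and -0.82) passed at both passages with the replicate block, and Tpsab1 (-1.14 and -1.72) at passage 10 with the block (adjusted p = 0.012) but not at passage 2 (0.0752 with the block). The chymase gene Cma1 (-0.64 and -0.91) and the solute carrier gene Slc45a3 (-0.87 and -0.83) did not pass with or without it (adjusted p = 0.264 and 0.0915 for Cma1 and 0.153 and 0.119 for Slc45a3 with the block). Of the 6 eosinophil genes, 5 were lower at passage 2 (median -1.08) and 4 at passage 10 (median -0.39). Epx, at -2.96 and -1.49, did not pass, and at passage 10 Ear6 (0.68) and Siglecf (0.38) had positive differences. Of the 3 basophil genes, Cd200r3 was at -0.04 and 0.16, Prss34 at 0.45 and 0.38 and Mcpt8 at -0.01 and 0.05, none of them passing. The standard error of Mcpt8 was 0.07 in the fit with the block. Its mean signal of 13.1 lay near the top of the arrays, which may have hidden a difference. Hdc of the fixed list, with a mean of 13, still differed by -0.32 and -0.28, and whether Mcpt8 was limited in this way was not tested. Itga2 (-2.00 and -2.47) and Fcer1a (-0.69 and -2.48) of the fixed list were not sorted among the 3 basophil genes. The small sorted groups therefore do not show that basophil genes were unchanged. The mean of the whole list was lower, with a difference of -0.58 ± 0.04 (SD over 3 pairs) at passage 2 and -0.59 ± 0.43 at passage 10, where the pairs ran from -0.996 to -0.145.

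The fall of the mast cell, basophil and eosinophil list might come from fewer cells of 1 population that carries all of its genes and is their only source. At passage 10, 15 of the 23 members below log2 12 lay over 2 standard errors (fit with the replicate block) from their median of -0.46. At passage 2, 11 did so from -0.52. The members thus did not move by 1 amount. The list joins genes of several cell types, so unequal moves were likely beforehand and do not decide the question. Whether mast cell-like cells were fewer or made less of these RNAs was not tested, since the 9 genes were picked after their values were seen. The carboxypeptidase gene Cpa3, left out of the 9, lay at 13.4, near the top of the arrays at 13.6, with a difference of 0.00 at both passages. The 28 members are by definition those that passed the filter, and 5 of them are also in other lists. The sort against CD11b and Gr1 would not remove mast cells. 4-OHT and Cre activity go with the genotype in every sample and stay open for every genotype difference.

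A second pattern lay in 5 predicted Eif1a-like genes of chromosome 12, singled out after their values were seen. At passage 10 Gm2016 (1.79, adjusted p = 0.0199), Gm2022 (3.17, 0.00674), Gm2035 (1.55, 0.0405), Gm2046 (2.96, 0.00479) and Gm5662 (4.26, 0.0072) were higher in Tet2-/- cells, and at passage 2 they differed by 1.08 to 2.22 without passing (0.134 to 0.172). With the replicate block Gm2022 (0.0422), Gm2035 (0.0422) and Gm2046 (0.0418) passed at passage 2, Gm2016 (0.123) and Gm5662 (0.0625) did not, and all 5 passed at passage 10. Such genes are known from 2-cell embryos. Of other genes of the wider program of that stage, 6 rows passed the filter. They differed by -0.35 to 0.31 at passage 2 and -0.23 to 0.21 at passage 10. The highest plus 2 standard errors (0.72 and 0.60) lay below the smallest difference of the Eif1a-like genes (1.08 and 1.55). This argues only against a rise of these 6 rows as large as that of the Eif1a-like genes. Those genes were singled out for large differences, so a smaller rise of the program is not excluded. Among the 6 rows Tdpoz2 (5.01), Usp17le (5.34) and Zscan4d (5.45) had means below the array medians. The 13 other rows of the program lay below the filter and exclude nothing. The parent genes Eif1a (0.03 and -0.12) and Eif1ax (0.17 and -0.08) did not follow. The copies may be read by each other's probes, since their deviations from the group means had a median correlation of 0.434, above the 95th percentile of 0.295 of 1000 random sets, but shared regulation would give this too.

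For the average of both genotype effects 290 genes passed, a count that was 98 to 496 without single arrays. Since the arrays pair by replicate number, the real grouping is compared with the combinations of splits within the passages that part all pairs. There are 16 of these when a combination and its mirror, with the groups of 1 passage swapped, count as 1 at the larger of their gene counts. Counted so, they are too few for a share under 0.05. The highest other gave 1 gene, and 1 of 16 gave as many as the real one. Among all 100 combinations the highest other gave 32. The correlation of the genotype effects was 0.582. Among the 15 others of the 16 the largest in size was negative (-0.482) and the largest positive one was 0.328, so that 1 of 16 gave as much in size. Among all 100 the highest other was 0.579, nearly the same.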
